A study of Homo sapiens with 12 samples.

How the data were processed

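Total RNA from 12 samples of HCT-116 xenograft tumours was labelled with biotin as cRNA and hybridised to Illumina expression beadchips, per the labels. The deposited value table holds probe intensity on a linear scale, and the authors' sorted columns differ by at most 1.28%, which is what quantile normalisation between arrays gives. Intensities ran from 86 to 21530.9, and the medians of the 12 columns lay between 117 and 117.1. No background subtraction was visible in them, so fold changes of dim genes are understated, and whether another scaling step was applied stays unknown. The scanner software and normalisation tool are not given in the sources used here. A second deposited table with signal and detection p-value holds 24 columns of per-sample values whose names match no sample label, and none of them was used.

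The fit planned before the data were examined started from neqc-normalised signals and a filter on detection p. Both need the unmapped columns, so log2 of the deposited intensities was analysed instead, with an intensity filter in place of the detection filter. Probes were kept where the intensity exceeded 120.3 in at least 3 of 12 arrays, a value 1.645 SD above the background mode of 108.6, which left 24118 probes. Of all probes, 30113 had 1 gene symbol, 8 several and 17202 none in the annotation used here. For 30074 probes the gene identifier was found in the RefSeq table of assembly GRCh38.p14, and 0 symbols needed an update. The brightest probe of each gene was kept, which gave 12988 named genes and 6640 unnamed probes.

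Groups were taken from the titles and characteristics of the samples. Nothing in the labels says whether replicates came from separate tumours or animals, so p-values measure only the spread between these samples, which may be technical. All 12 arrays were fitted with 4 group means in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, 8 residual degrees of freedom, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The planned comparisons were the plasmid difference without and with drug, the drug difference under each plasmid label, and the difference of the drug differences. The averages of the plasmid and of the drug differences were added after the planned comparisons had given no call. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 under Python 3.11.15.

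Named genes followed a fixed rule for the planned comparisons, used for the averages too: ERCC1, then the 10 largest rises and 10 largest falls among calls with non-overlapping groups, or, with fewer than 10 calls, the 5 higher and 5 lower genes with the smallest unadjusted p, given as values. Up to 4 members of each list were named by smallest p. Symbols without a known function could be counted without being named. Except for the averaged drug comparison, only some of the genes that the rule took are named below. The 31 fixed lists were p53 targets, nucleotide excision repair, crosslink repair and recombination, apoptosis regulators, platinum transport, G1/S, G2/M, ribosomal proteins, ribosome biogenesis, hypoxia, housekeeping, metallothioneins, ATF4 and unfolded protein response, heat shock, NRF2 targets, immediate early genes, MAPK pathway output, EGFR family, NF-kB targets, interferon response, Wnt targets, cholesterol synthesis, epithelial and colon differentiation, epithelial-mesenchymal transition, and markers of fibroblasts, endothelium, macrophages, neutrophils, erythrocytes, skeletal muscle and adipocytes. Lists with at least 5 measured members were tested with limma's camera with an estimated inter-gene correlation, and with the preset correlation of 0.01 and fry as alternatives. Members were also counted with p adjusted over their list alone. That adjustment does not cover the other lists or comparisons, and some lists share members. How many such calls other sets of genes would give was not tested, so these counts are descriptions.

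The steps were tested on simulated data made from the residuals of the real arrays, dealt at random to the groups, with 200 changed features per draw and 20 draws over 19628 features. For the drug difference under the control label, 63.7%, 89.3% and 97.8% of features changed by 1.5-, 2- and 3-fold were recovered, and for the average over plasmids 84.6%, 96.7% and 99.6%. The 3 sizes were planted together, so the larger changes eased the adjusted threshold for the smaller. They were added in full on the log2 scale, while real changes of dim genes are understated. These shares may therefore be higher than in the real comparisons. False calls had a median of 1 per draw in both, with a highest count of 582 and 938, in draws that kept the correlation between genes. Each draw also held a list of 30 further features raised by 1.5-fold, which had an unadjusted camera p under 0.05 in 20 of 20 draws for both. Its members were drawn at random, so this does not show how often a list of correlated genes would be called. Alternatives covered the scale, background correction, probe filter, probes per gene, variance model, array weights, replicate block, arrays in the fit, a 2-fold threshold and leaving out each array in turn. A slide block and the settings that need detection p were not run.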

Results

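Gene expression was measured in tumours grown in immunodeficient scid mice from HCT-116, an established human colorectal cancer cell line. The cells carried either a control plasmid or a plasmid coding for ERCC1, a subunit of the nuclease that cuts DNA beside platinum lesions during nucleotide excision repair. Mice were left untreated or were given oxaliplatin, a platinum drug that crosslinks DNA, at 2 mg/kg, and tumours were recovered 2 h later. The labels name no vehicle for the untreated mice. Drug differences below can therefore not be told apart from differences due to dosing or handling. The 12 arrays fell into 4 groups of 3, and 24118 probes (51.0%) were above the dim threshold. After 1 probe was kept per named gene, 19628 features were tested. The number of arrays limits the precision: the median 95% interval of a log2 difference between 2 groups reached 0.22 to either side.

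The ERCC1 transcript was examined first, because it checks the plasmid labels. Its brightest probe, ILMN_2277676, gave a deposited intensity of 686 ± 126 (SD, n = 3) in control untreated arrays, 514 ± 55.2 in control oxaliplatin arrays, 594 ± 130 in ERCC1 untreated arrays and 481 ± 31.7 in ERCC1 oxaliplatin arrays. The difference between arrays labelled ERCC1 and arrays labelled control was -0.22 on the log2 scale without drug (95% interval -0.57 to 0.14) and -0.09 with drug (-0.45 to 0.26). Leaving out 1 array moved the former to between -0.37 (without ERCC1 untreated 3) and -0.055 (without ERCC1 untreated 2), with -0.073 without control untreated 1. It moved the latter to between -0.15 (without control oxaliplatin 1) and -0.0083 (without control oxaliplatin 3), with -0.146 and -0.059 without ERCC1 oxaliplatin 1 and 2. The probe ILMN_2377496 gave -0.21 and -0.04, ILMN_1652369 gave -0.01 and -0.02, and ILMN_1797172 gave 0.09 and -0.13. The arrays of ILMN_1652369 (147 to 203) and ILMN_1797172 (123 to 171) lay close to the dim threshold of 120.3, where fold changes are understated. The measured transcript was therefore not shown to be higher under the ERCC1 label, and every direction between plasmids below is one between arrays labelled ERCC1 and arrays labelled control. The probe sequences were not used here, so it is not known whether any of these probes reads RNA made from the plasmid. One label field also describes all 12 samples as cells with the ERCC1 plasmid, while another names the control plasmid for 6 of them.

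**Figure D1:**
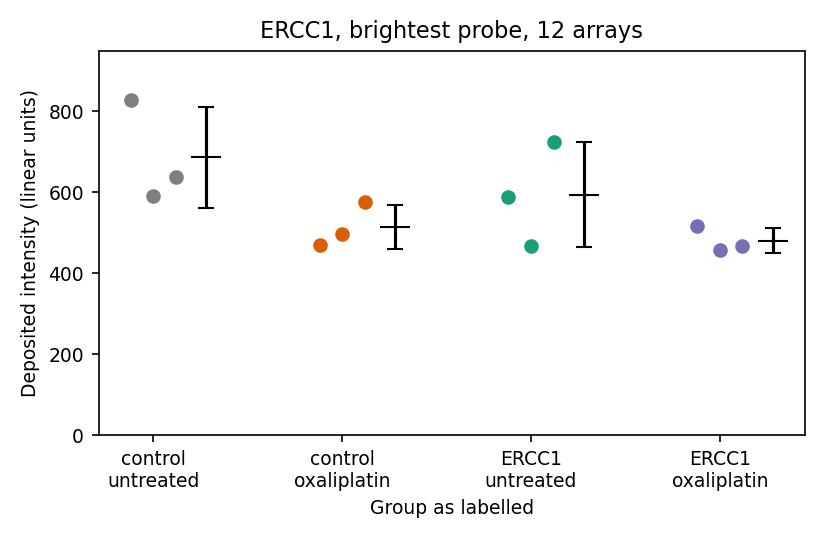
Deposited intensity of the ERCC1 probe ILMN_2277676 (vertical axis, linear units) in each of the 12 arrays by labelled group, with 1 point per array and the mean ± SD of 3 arrays beside the points. The arrays spanned 459 to 829, and the groups labelled ERCC1 did not lie above those labelled control.

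The arrays resembled each other by treatment. For 10 of 12 arrays the nearest array by correlation across features had the same treatment, against 5.45 expected by chance. The nearest array was under the same plasmid label for 1 of 12, against 5.45 by chance, and in the own group for 0 of 12, against 2.18. Similarity within treatments exceeded that between treatments in an exact one-sided test over all splits of 6 against 6 arrays (p = 0.00433, adjusted p = 0.013 over 3 tests), and similarity within plasmids did not exceed that between plasmids (exact one-sided p = 0.677). On PC1, which held 30.4% of the variance, oxaliplatin arrays scored 11.2 ± 5.54 (SD, n = 6) and untreated arrays -11.2 ± 11.6 (exact two-sided permutation p = 0.005, adjusted p = 0.03 over 6 tests, the smallest p these relabellings can give). The array control untreated 1 stood farthest out at -28.9, and ERCC1 untreated 2 lay among the treated arrays at 7.31.

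**Figure D2:**
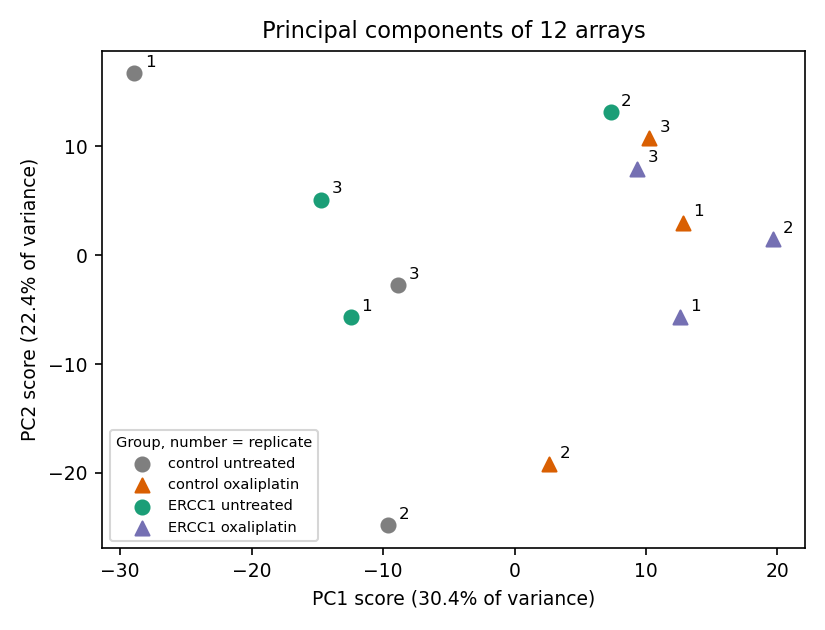
Scores of the 12 arrays on PC1 (horizontal axis, 30.4% of the variance) and PC2 (vertical axis, 22.4%), in arbitrary units. Circles are untreated arrays, triangles are oxaliplatin arrays, colours are the 4 labelled groups and numbers are replicates. The 6 oxaliplatin arrays lay on the right, with ERCC1 untreated 2 beside them.

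Without drug, no gene passed the test between arrays labelled ERCC1 and arrays labelled control. Some of the 10 genes that the naming rule took are given as values, and these are not the ones with the smallest unadjusted p. WASHC5, a subunit of the WASH complex that acts on endosomal actin, was at 625 ± 64.9 against 485 ± 35.9 (SD, n = 3), and PERP, a p53-regulated membrane protein of desmosomes, at 2791 ± 213 against 2174 ± 262. H19, an imprinted long noncoding RNA, was at 187 ± 20.8 in arrays labelled ERCC1 against 229 ± 6.85. Limma called 0 of 19628 features (lowest adjusted p = 0.999), and 587 had an unadjusted p under 0.05, where 981 would be expected by chance. Of the 7 measured metallothionein-list genes, which bind or export metals, 6 were lower in arrays labelled ERCC1, with a median difference of -0.50. MT1X was at -0.76 ± 0.28 (log2 difference ± SE) and MT1G at -0.57 ± 0.20, and 0 members passed over all genes or adjusted over the list alone. That list was called by camera with its preset correlation (adjusted p = 0.00208) and lost with an estimated one (adjusted p = 0.856 with an estimated correlation). The array control untreated 1 held the highest metallothionein level of all 12 (0.75 from their mean, log2), and ERCC1 untreated 2 the lowest (-0.45).

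Under oxaliplatin, again no gene passed the test between arrays labelled ERCC1 and arrays labelled control. ABHD10, a mitochondrial thioesterase, was at 1849 ± 64.6 against 1411 ± 151 (SD, n = 3). LYAR, a nucleolar protein, was at 1503 ± 28.5 against 2104 ± 330, and YY1, a zinc finger transcription factor, at 2277 ± 150 against 2776 ± 224. Limma called 0 features (lowest adjusted p = 1), with 413 at an unadjusted p under 0.05. Interferon response genes were lower in 25 of 28 measured members, with a median of -0.14, and IFIT1 at -0.56 ± 0.42 and ISG15 at -0.37 ± 0.30. Immediate early genes, which respond to growth and stress signals within minutes, were lower in 18 of 26, with ZFP36 at -0.28 ± 0.12 and DUSP1 at -0.25 ± 0.12. In both lists 0 members were called over all genes or adjusted over the list alone. Both were called with the preset correlation (adjusted p = 0.0267 and 0.0251), and neither with an estimated one (adjusted p = 0.969 and 0.786 with an estimated correlation). The array ERCC1 oxaliplatin 3 had the lowest interferon response level of the 12, at -0.63 from their mean (log2). ERCC1 oxaliplatin 1 and 2 were at 0.24 and -0.11, and control oxaliplatin 1, 2 and 3 at -0.24, 0.16 and 0.12. The lower mean level of this list under the ERCC1 label therefore rests on that array.

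In the arrays labelled control, no gene passed the adjusted threshold between oxaliplatin and untreated arrays, and values are given for some genes that the naming rule took. EXT2, which polymerises heparan sulfate, was at 524 ± 17.4 with drug against 393 ± 18.6 without (SD, n = 3). CTNNAL1, an alpha-catenin-like protein, was at 1663 ± 154 against 1144 ± 115, and PAPSS1, which makes the sulfate donor PAPS, at 1728 ± 50.2 against 1253 ± 125. RPP21, a subunit of ribonuclease P, was at 1381 ± 47.1 against 2272 ± 336, and MTFP1, a protein of the mitochondrial inner membrane, at 615 ± 28.1 against 892 ± 35.1. Limma called 0 features (lowest adjusted p = 0.164), while 2600 (13.2%) had an unadjusted p under 0.05 and 3219 (16.4%) had groups that did not overlap, where chance gives 10% on average. With correlated genes 1 comparison can lie away from that average, and the plasmid comparisons had 6.78% without drug and 7.89% with drug. G1/S genes were higher in 24 of 28 members and ribosomal proteins lower in 28 of 37, with preset adjusted p of 0.000301 and 0.00302, and metallothioneins, G2/M, hypoxia, heat shock and housekeeping genes were also called with the preset correlation. None of the 7 lists was called with an estimated correlation (adjusted p = 0.583 with an estimated correlation for each). Adjusted over the list alone, 0 G1/S genes were called, 1 ribosomal protein rose and 1 fell, 3 G2/M genes and 1 hypoxia gene rose, MT1G (-0.71) and MT1X (-0.96) fell, and 0 heat shock or housekeeping genes were called. The p53 target BAX was at -0.65 and also fell on that adjustment, with 0 calls over all genes. The metallothionein level was 0.75 in control untreated 1 (log2, from the mean of all arrays), against 0.33 and 0.02 in control untreated 2 and 3. Limma's fry called none of the 7 lists for a shift one way, and 4 of them for change in either direction, which does not compare a list with other genes. The ERCC1 transcript was at -0.41 ± 0.16 (limma adjusted p = 0.32).

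In the arrays labelled ERCC1, no gene passed the adjusted threshold between oxaliplatin and untreated arrays. CTNNAL1 was at 1792 ± 46.3 with drug against 1234 ± 45.5 without (SD, n = 3), and MYBL1, a transcription factor of the MYB family, at 426 ± 44.6 against 294 ± 30.6. DDIT3, the stress-induced transcription factor CHOP, was at 285 ± 15.5 against 431 ± 34.7, and MRPS6, a protein of the mitochondrial ribosome, at 945 ± 66.2 against 1355 ± 117. Limma called 0 features (lowest adjusted p = 0.336), with 1914 (9.75%) at an unadjusted p under 0.05 and 3130 (15.9%) with groups that did not overlap, against 10% by chance on average. G1/S genes were higher in 24 of 28 members (preset adjusted p = 0.00142) and hypoxia genes in 23 of 29 (preset adjusted p = 0.0157), and G2/M genes, ribosomal proteins and housekeeping genes were called with the preset correlation as well. None of these 5 lists was called with an estimated one (adjusted p = 0.809 with an estimated correlation for each). Adjusted over the list alone, which leaves out the other lists, CDT1 (0.41) rose among G1/S genes. LOX (0.41) and BNIP3L (0.62) did so among hypoxia genes, with 0 calls over all genes. On that adjustment 1 G2/M gene, 0 ribosomal proteins and 3 housekeeping genes also rose. The hypoxia level of all arrays was highest in ERCC1 oxaliplatin 2 (0.19 from their mean, log2) and lowest in ERCC1 untreated 2 (-0.16). ERCC1 oxaliplatin 3 was at -0.06.

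The series asks about an effect of the drug in cells with the ERCC1 plasmid, and the difference between the drug effects in the 2 plasmid groups compares that with the control plasmid. MLLT10, a chromatin-associated protein, was at 647 ± 37.7 with drug against 501 ± 30.8 without in arrays labelled control, and at 579 ± 35.4 against 619 ± 44.4 in arrays labelled ERCC1 (SD, n = 3). YY1 in the same order was at 2776 ± 224 against 2246 ± 24.7 and at 2277 ± 150 against 2455 ± 153. The drug effect on MED23, a subunit of Mediator, differed by 0.49 ± 0.13 (log2 ± SE). None of these differences passed the test: limma called 0 features (lowest adjusted p = 1), with 345 (1.76%) at an unadjusted p under 0.05. The median 95% interval of this difference reached 0.32 to either side on the log2 scale, which limits the differences that could be detected. None of the lists tested was called with either correlation (lowest preset adjusted p = 0.329, for metallothioneins). Across features, the drug effects in the 2 plasmid groups had Pearson r = 0.69 and Spearman rho = 0.61, and 68.1% had the same sign. Genes are not independent replicates, and relabelling the arrays gave a permutation p of 0.03, two-sided (adjusted p = 0.06 over 4 correlations). The plasmid effects with and without drug had r = 0.24 (permutation p = 0.46, two-sided). That correlation was -0.042 without control oxaliplatin 2, 0.10 without control untreated 1, 0.08 without ERCC1 oxaliplatin 2 and 0.11 without ERCC1 untreated 2.

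**Figure D3:**
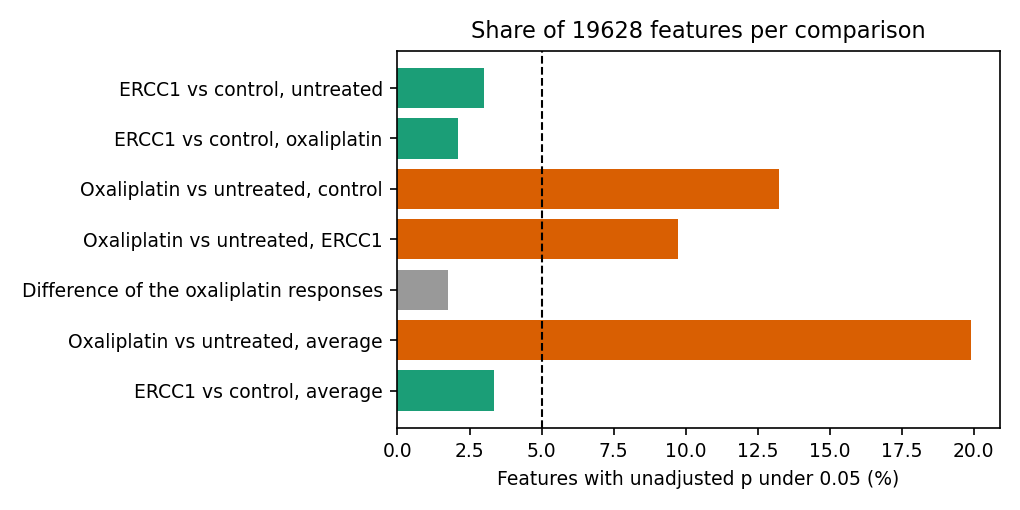
Percentage of features with an unadjusted limma p under 0.05 (horizontal axis) in each of 7 comparisons, with the dashed line at 5, the share expected without any difference. The drug comparisons reached 13.2% and 9.75% and their average 19.9%, while the plasmid comparisons and the difference of the drug effects lay below the line. Wrongly labelled arrays can pass the line too: the highest other relabelling gave 3878 features for the average, against 3907 with the real labels.

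Because neither drug comparison gave a call and PC1 followed treatment, the drug effect was also averaged over the plasmids, a comparison chosen after seeing those results. In this average 163 features rose and 153 fell, none by 2-fold, with changes from 1.17- to 1.76-fold. CTNNAL1 rose by 0.54 ± 0.06 (log2 change ± SE, limma adjusted p = 0.0278), KIF23, a kinesin needed for cytokinesis, by 0.51 ± 0.08 (adjusted p = 0.0312), and CMTM6, a membrane protein that stabilises PD-L1, by 0.52 ± 0.08 (adjusted p = 0.0312). MIX23 fell by 0.69 ± 0.10 (adjusted p = 0.0312), ATP6V0E1, a subunit of the proton pump of lysosomes, by 0.59 ± 0.08 (adjusted p = 0.0278), and MGMT, which removes alkyl groups from guanine in DNA, by 0.61 ± 0.10 (adjusted p = 0.0316). Over all features, 715 (3.64%) had drug and untreated arrays that did not overlap, in the same direction under both plasmid labels, where chance gives 0.5% on average. The count rested on single arrays. It was 16, 0 and 0 without control oxaliplatin 1, 2 and 3, 15, 1225 and 35 without control untreated 1, 2 and 3, 0, 0 and 557 without ERCC1 oxaliplatin 1, 2 and 3, and 0, 1134 and 0 without ERCC1 untreated 1, 2 and 3. It was also 0 after normexp background correction. Simulated arrays that kept the correlation between genes gave a median of 1 false call per draw. False calls occurred in 10 of 20 draws, with up to 938 in a draw. Each draw also held 200 changed features and a list of 30 raised ones, so these are not counts without any change.

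**Figure D4:**
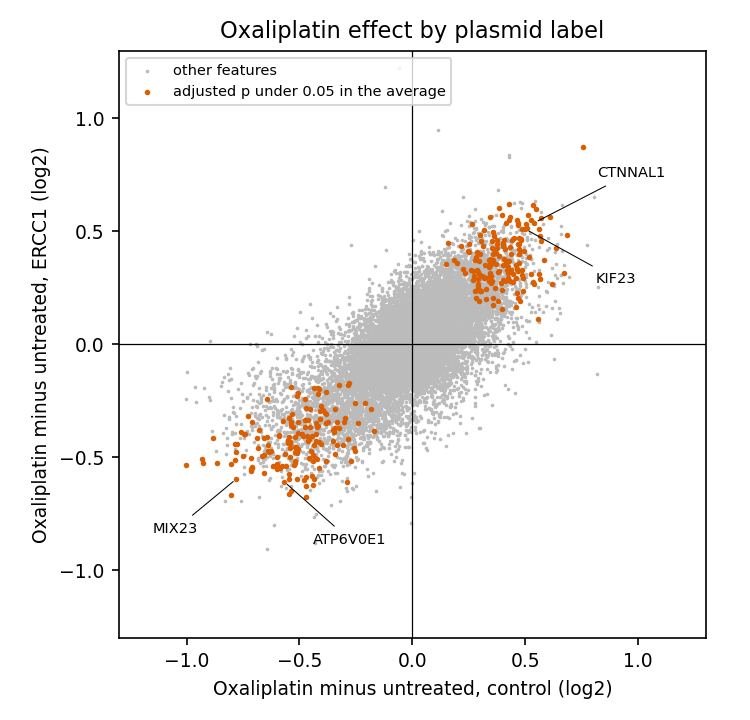
Log2 difference between oxaliplatin and untreated arrays for each feature in arrays labelled control (horizontal axis) and labelled ERCC1 (vertical axis). Grey points are other features and orange points are the 316 with an adjusted p under 0.05 in the average, a threshold that itself favours features with the same sign in both groups (r = 0.69 over all features).

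The remaining genes that the naming rule took from this average covered several processes. Those that rose were PMEPA1 by 0.58 ± 0.11, MAPKAPK3 by 0.54 ± 0.11, STAG2, a cohesin subunit, by 0.53 ± 0.11, UHRF1, which guides maintenance DNA methylation, by 0.53 ± 0.11, SP3 by 0.52 ± 0.10, CPSF1 by 0.51 ± 0.11 and PGM1 by 0.51 ± 0.10. Those that fell included C12orf57 by 0.74 ± 0.13, DNPH1 by 0.70 ± 0.14 and LAMTOR2, which helps to anchor mTORC1 to lysosomes, by 0.67 ± 0.12. The others that fell were MRPL2, of the mitochondrial ribosome, by 0.63 ± 0.10, EMC6 by 0.61 ± 0.11, RPL26L1 by 0.59 ± 0.11 and ZNF593 by 0.58 ± 0.11. Their limma adjusted p lay between 0.0312 and 0.0476. ERCC1 was at -0.34 ± 0.11 (adjusted p = 0.124).

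The calls among DNA damage genes in the average over plasmids are given here. Of all 12988 named genes, 142 were called upward and 124 downward in it. Whether a list held more or fewer calls than that was not tested. Counts adjusted over a list alone were not adjusted across the lists. Of 26 measured p53 targets, 15 were higher and 11 lower, and the 2 called over all genes both fell: BAX, a pore-forming apoptosis effector, by 0.53 ± 0.10 (log2 change ± SE) and GDF15, a secreted stress cytokine, by 0.38 ± 0.08. Adjusted over the list alone, 1 rose and 3 fell. Of 37 nucleotide excision repair genes 0 were called over all genes, and 2 rose and 1 fell adjusted over the list alone, with RPA3 at -0.51 ± 0.13. Of 26 crosslink repair and recombination genes, NBN, of the break-sensing MRN complex, rose by 0.39 ± 0.06 and MAD2L2, a subunit of translesion polymerase zeta, fell by 0.40 ± 0.08, and adjusted over the list alone the counts were also 1 and 1. BAX was also the member called among 21 apoptosis regulators, where 3 fell adjusted over the list alone. Of 10 platinum transport genes, LRRC8A, a subunit of an anion channel that passes platinum drugs, rose by 0.29 ± 0.06, and 1 rose and 1 fell adjusted over the list alone.

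Cell cycle genes lay on the higher side with oxaliplatin. G1/S genes were higher in 23 of 28 members (median 0.15), CDT1, which licenses replication origins, rose by 0.35 ± 0.07, and 2 were called over all genes and 10 adjusted over the list alone, all upward. G2/M genes were higher in 24 of 30 (median 0.11). KIF23 and TOP2A, which untangles replicated DNA and rose by 0.33 ± 0.06, were called, and 7 rose and 3 fell adjusted over the list alone. Ribosomal proteins were lower in 28 of 37 (median -0.12). RPL14 fell by 0.73 ± 0.15, and adjusted over the list alone 1 rose and 2 fell. Ribosome biogenesis genes were higher in 16 of 28. GAR1 and FBL, components of small nucleolar ribonucleoproteins, fell by 0.37 ± 0.06 and 0.31 ± 0.06, with 4 up and 4 down adjusted over the list alone. Hypoxia genes were higher in 26 of 29 (median 0.13) and housekeeping genes in 10 of 12 (median 0.11), with 0 calls over all genes and 3 and 5 adjusted over the list alone. Metallothioneins were lower in 6 of 7 (median -0.31) with 0 calls over all genes or adjusted over the list alone. The array control untreated 1 had the highest ribosomal protein and metallothionein levels of the 12. Across the 12 arrays the correlation of the level with PC1 was 0.82 for G1/S genes, 0.59 for hypoxia genes, -0.63 for ribosomal proteins and -0.86 for metallothioneins. These lists except ribosome biogenesis were called with the preset correlation (adjusted p from 8.27e-05 to 0.0222), and none was with an estimated one (adjusted p = 0.671 with an estimated correlation for each). An exact two-sided permutation test within plasmids was run for 6 of the 31 fixed lists and for 11 symbol groups given below. G1/S genes passed it (adjusted p = 0.0283 over 17 groups). Ribosomal proteins (0.0661), hypoxia genes (0.0695), metallothioneins (0.128), interferon response genes (0.425) and erythrocyte markers (0.15) did not. The averaged comparison was chosen after seeing the data.

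Calls in the stress and signalling lists are likewise given without a test against the counts over all named genes. Of 23 ATF4 and unfolded protein response genes 14 were higher. DDIT3 fell by 0.55 ± 0.08 and MANF, a secreted chaperone-like factor, by 0.45 ± 0.09, and 4 rose and 3 fell adjusted over the list alone. In the other lists 0 members were called over all genes. Adjusted over the list alone, 2 of 17 heat shock genes rose, 1 of 18 NRF2 targets rose, 1 of 26 immediate early genes (MYC, at 0.39 ± 0.09) rose, and of 15 NF-kB targets 2 rose and 3 fell. The same adjustment gave 1 rise among 14 Wnt targets, 1 among 17 cholesterol synthesis genes, 1 among 12 epithelial and colon differentiation genes, and 1 rise and 1 fall among 11 epithelial-mesenchymal transition genes. It gave 0 among 15 MAPK pathway output genes, 10 EGFR family genes and 28 interferon response genes. Camera called none of these lists in the average with either correlation.

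Markers of other cell types that a xenograft can hold were measured in part. Whether these human probes read mouse transcripts was not tested, so the markers do not show how much host tissue was present. Of the listed human symbols, 10 of 19 fibroblast, 4 of 14 endothelium, 8 of 16 macrophage, 5 of 10 neutrophil, 5 of 11 erythrocyte, 3 of 13 skeletal muscle and 6 of 8 adipocyte markers were measured. In the average over plasmids 0 were called over all genes. Adjusted over the list alone, CSF1R (0.28 ± 0.07) rose among macrophage markers and CFD (-0.50 ± 0.12) fell among adipocyte markers, and 0 passed in the other lists. All 5 erythrocyte markers were lower, with a median of -0.27 and no call (adjusted p = 0.671 with an estimated correlation). The endothelium and skeletal muscle lists had too few members for camera.

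The plasmid difference was averaged over treatments in the same way. ABHD10 was at 0.34 ± 0.07 (log2 difference ± SE), PERP at 0.31 ± 0.07 and FAM110A at -0.27 ± 0.05, and none of these passed the test. Limma called 0 features (lowest adjusted p = 0.999), with 657 (3.35%) at an unadjusted p under 0.05. Metallothioneins (6 of 7 lower), interferon response genes (24 of 28 lower), immediate early genes (18 of 26 lower) and NF-kB targets (13 of 15 lower) had 0 members called over all genes or adjusted over the list alone. They were called with the preset correlation (adjusted p from 0.0113 to 0.0393), and none with an estimated one (adjusted p from 0.908 to 0.939 with an estimated correlation). Single arrays stood apart in these lists. The interferon response level was lowest in ERCC1 oxaliplatin 3 (-0.63 from the mean of all arrays, log2). The metallothionein level was highest in control untreated 1 (0.75) and lowest in ERCC1 untreated 2 (-0.45).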

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

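The averaged comparisons, normexp, the intensity filters and the fit on treatment alone were chosen after seeing the data. The 5 planned counts and the averaged plasmid count were 0 in limma under every alternative run. The averaged drug count of 316 was 1387 with array weights, 495 with a stricter filter, 735 with plasmid left out of the fit, 184 with no filter, 100 with trend and robust variance, 0 with normexp and 0 with a 2-fold threshold, while all probes (345) and log2 of intensity plus 16 (264) stayed within 1.5 times. Leaving out 1 array gave 0 to 1225: without control oxaliplatin 1, 2 and 3 it was 16, 0 and 0, without control untreated 1, 2 and 3 it was 15, 1225 and 35, without ERCC1 oxaliplatin 1, 2 and 3 it was 0, 0 and 557, and without ERCC1 untreated 1, 2 and 3 it was 0, 1134 and 0. Fewer arrays alone lower such a count, but the rises have no tested cause. The 20 named genes of that average gave 380 values over the alternatives, of which 158 kept their call, 222 lost it and 0 reversed. With the replicate block the count was 0. The numbers do not pair the samples: residual correlations of same-numbered arrays ran from -0.59 to 0.52, 5 of 18 were over 0.1, and 2 of 12 arrays correlated best with their own number.

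Camera called 15 list tests in the 5 planned comparisons with the preset correlation and 0 with an estimated one or with the replicate block. Fry's test for a shift one way called 0 lists in every comparison. Its test for change in either direction called 10 lists for drug under the control label, among them apoptosis regulators (adjusted p = 0.00248) and G2/M genes (adjusted p = 0.0192), 15 in the drug average and 0 in the other 5 comparisons. The correlation of the drug effects (0.69) was 0.57 with normexp and 0.49 to 0.75 with 1 array left out. That of the plasmid effects (0.24) ran from -0.042 without control oxaliplatin 2, where it turned negative, to 0.33, and was 0.10 without control untreated 1, 0.08 without ERCC1 oxaliplatin 2 and 0.11 without ERCC1 untreated 2. ERCC1 read by ILMN_1797172 was at 0.085 for arrays labelled ERCC1 without drug and at 0.13 for drug under the control label, opposite in sign to the brightest probe. With 1 array left out, the brightest probe ran from -0.51 to -0.26 (without control untreated 1) for drug under the control label, and from -0.44 (without ERCC1 untreated 2) to -0.13 (without ERCC1 untreated 3) for drug under the ERCC1 label. The cause was not tested in any of these cases. The neqc, detection p and slide settings were not run, and signal close to background limits what dim probes can show.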

Other observations

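Besides the fixed lists, 11 gene groups defined by the start of the symbol were examined in the 2 drug comparisons and their average after the named genes had been seen, and 3 of them concerned mitochondria. All tests of the mitochondrial, ERCC1 and nearest-array patterns below were chosen after the result was seen, except the background test, whose prediction was written before its value. In the drug effect averaged over plasmids, 30 of 33 complex I genes of the respiratory chain were lower, with a median of -0.38 on the log2 scale. NDUFB11 fell by 0.77 ± 0.13 (log2 change ± SE) and NDUFS3 by 0.41 ± 0.07. Mitochondrial ribosome genes were lower in 68 of 77 (median -0.30), with 6 called, and cytochrome oxidase, complex III and ATP synthase genes in 32 of 37 (median -0.31), where ATP5F1D fell by 0.56 ± 0.10. Spliceosomal Sm and LSm genes were lower in 19 of 25 and RNA polymerase II subunits in 12 of 16, and histones in 25 of 30, while 5 of 6 MCM helicase genes and 20 of 30 kinesins were higher. The array control untreated 1 was the highest of the 12 in each of these groups that was lower with drug, and the lowest in MCM helicase genes and kinesins. In each of the groups the untreated arrays spanned at least 1.46 times the drug difference. Their levels also followed PC1 across the arrays. The correlation was -0.96 for complex I, -0.87 for the mitochondrial ribosome and -0.89 for the cytochrome oxidase group. It was -0.91 for Sm and LSm genes and for RNA polymerase II, -0.78 for histones, 0.70 for MCM helicase genes and 0.74 for kinesins. These groups may therefore share a component and need not be separate shifts. Proteasome subunits (21 of 34 lower, median -0.07), EIF3 subunits (5 of 14 lower, median 0.10) and ZNF genes (148 of 337 lower, median 0.01) had a two-sided p of 0.36, 0.39 and 0.94 in the exact permutation test and did not pass it. The exact test was also adjusted over 17 groups, these 11 and 6 of the fixed lists. On that adjustment MCM helicase genes (adjusted p = 0.0695) and kinesins (adjusted p = 0.0638, and 0.0471 over the 11 groups alone) did not pass it either. Adjusted over the 11 groups, camera called none of them (lowest adjusted p = 0.204 with an estimated correlation), although with the preset correlation it called all except proteasome subunits, EIF3 subunits and ZNF genes (highest adjusted p among those called = 0.0106).

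The lower complex I level of oxaliplatin arrays differed by -0.34 between the means of 6 and 6 arrays. Background left in the deposited intensities stays open: the median was -0.43 after normexp, but the arrays are quantile normalised, so normexp changes all of them almost alike and can hardly turn the sign. Spread unrelated to treatment stays open as well: the exact permutation within plasmids gave a two-sided p of 0.01 (adjusted p = 0.0283 over 17 groups), but the group was chosen after genes of the same comparison had been seen. A state of the tumour or RNA that also varies without the drug stays open too: the untreated arrays spanned 1.66 times the drug difference, and 0.946 times without control untreated 1, where the level was the highest of all 12 arrays, and the rule for reading this ratio was tightened after its value was seen. A drug effect at 2 h is a hypothesis that cannot be told apart from these here.

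The ERCC1 transcript was not shown to be higher in arrays labelled ERCC1, although ILMN_1797172 was at 0.085 without drug. The widest gap between neighbouring arrays in any ERCC1 probe was 0.257 on the log2 scale, but mislabelled arrays stay open, since arrays that all hold the same cells would leave no gap. Probes that do not read the plasmid RNA may explain the levels, and stay open too: the highest upper 95% bound of the fold over 4 probes and both plasmid comparisons was 1.26. That bound came from ILMN_1797172, whose arrays lay at 123 to 171, close to the dim threshold of 120.3. With no background subtracted, it understates the fold that could have been missed. A plasmid with little expression in these tumours was not tested.

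No array was closest to an array of its own group. Treatment labels unrelated to the arrays are argued against (exact one-sided p = 0.00433 over all splits). Plasmid labels unrelated to the arrays stay open (exact one-sided p = 0.677), and a plasmid without effect on transcripts gives that value too, so these cannot be told apart. That test looks only for greater similarity within plasmids. By chance 5.45 of 12 arrays would have their nearest array under the same plasmid label and 2.18 in their own group, against 1 and 0 here. Neither explanation predicts counts below chance, and the cause was not tested. A batch shared by all arrays of a replicate number is argued against by the median residual correlation of same-numbered arrays, -0.117. The 0.10 for other pairs is no independent comparison, because residuals cancel within each group. Same-numbered pairs ran from -0.59 to 0.52, so a batch shared by some of them stays open.

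Other splits of the arrays were counted for each comparison. For each of the 4 comparisons of 3 against 3 arrays, all 10 of 10 splits gave as many calls (0 in the real split, 0 at most in the others), and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split and the highest other gave 587 and 2320 for plasmid without drug, 413 and 1887 for plasmid with drug, 2600 and 2212 for drug under the control label, and 1914 and 1829 for drug under the ERCC1 label. For the difference of the drug effects 100 of 100 labellings, the real one among them, gave as many calls (real 0, highest other 316). The highest of these swaps treatment in 1 plasmid and is the averaged drug comparison itself. For the averaged plasmid effect 100 of 100 did (real 0, highest other 0). A real count of 0 is reached by every split, so these counts say nothing about chance. For the averaged drug effect 2 of 100 labellings, the real one being 1 of the 2, gave at least as many calls (real 316, highest other 724). That is a share under 0.05, for a comparison that was itself chosen after seeing the data. The other labellings were drawn at random and not all tried, so the share depends on the draw. The 724 came from exchanging ERCC1 untreated 2 with ERCC1 oxaliplatin 3. At an unadjusted p under 0.05 the real labels gave 3907 features for this average, and the highest other relabelling 3878.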
